A study of Homo sapiens with 4 samples.

How the data were processed

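Total RNA of hCMEC/D3 cells was hybridised to the Affymetrix Human Transcriptome Array after labelling from 100 ng of input, per the labels' protocols. The 4 arrays form 2 groups of 2, taken from the sample titles (E and NC). The values used are the log2 signals in the deposited table, which the authors made with RMA (robust multi-array average, which corrects background, quantile-normalizes and summarises probes) in Affymetrix Expression Console, per the submitters' processing notes; the versions, the annotation release and the genome build are not given in the sources used here. The sample descriptions name a gene-level summary, abbreviated sst-rma. RMA draws probes together into 1 value per transcript cluster, so probe-level differences, exons and splice forms were not analysed here, and a difference in total signal between arrays may have been removed before deposit. Scanner files were not used here.

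The table has 70523 rows. The 67528 transcript clusters were tested, and 2995 other probesets (controls, junctions and single probe regions) were left out of the main test; fitted by themselves, 0 of these passed an adjusted p of 0.05 in limma and 114 had an unadjusted p under 0.05. Genes were named from the platform annotation: 23781 clusters have 1 gene symbol, 1543 have several and were not given a single name, and 42204 have none listed here. Of 22465 distinct named genes, 22167 matched the gene table by gene identifier or symbol and took its current symbol. For a gene with several clusters, the one with the highest mean over all 4 arrays was used. Coordinates are not printed, since the builds could not be matched; chromosomes come from the cluster names.

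Group differences (E minus NC, log2) were fitted with lmFit and eBayes with an intensity trend (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all 67528 clusters, an adjusted p threshold of 0.05 and no filter on dim clusters. A second count used a log2 difference of at least 1 with an unadjusted p under 0.05. All p-values are two-sided and come from this model or from limma's set tests. A permutation test of 2 against 2 arrays cannot give a p below 0.333, so none was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

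The design, the alternatives and 27 gene lists were fixed before the data were examined. The lists cover tight junctions, endothelial identity, barrier transport, adhesion, migration, G1/S, G2/M, histones, interferon, NF-kappaB, unfolded protein, heat shock, p53, cholesterol, hypoxia, immediate early, YAP and TGF-beta, JAK-STAT, PI3K-Akt, Wnt, Notch and ribosomal protein genes, and markers of epithelial, mural, neural and blood cells. The list of mitochondrially encoded genes had fewer than 3 measured members under its symbols and was not tested, which left 26. Each list was tested with camera at a preset correlation of 0.01 on 1 cluster per gene, with Benjamini-Hochberg adjustment over the 26 lists; camera with an estimated correlation and fry, with its directional and its mixed test, were run beside it. After seeing the data, the mixed test was also run on 100 sets of 26 random lists of the same sizes, drawn from genes of similar signal, of which 29.3% had an unadjusted p under 0.05. Some genes are in more than 1 list. Members were also adjusted over their list alone, which does not correct for the number of lists. The bootstrap SE of a median comes from resampling its genes with replacement.

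The named genes follow a rule fixed with the design: CLDN5, then up to 12 protein-coding genes per direction past the threshold with both E arrays on 1 side of both NC arrays and a group mean above the median of all clusters, filled where fewer passed by the smallest unadjusted p among those with a log2 difference of at least 1, and from each list up to 4 members past the threshold or else the 2 with the smallest p. As 0 clusters passed, the filling gave only AMTN and POTEC, and every list gave 2 members. Other genes are named in the text as chosen after their values were seen; ISG15, MX1 and IFIT1 were added in this way as well.

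The steps were tested on simulated data with known answers, drawn from the fitted prior of the variances with 200 of 67528 clusters changed, in 20 simulations per size. At the adjusted threshold 0% of 1.41-fold, 0% of 2-fold and 89.2% of 4-fold differences were recovered. For the lists, 22465 genes were simulated 50 times: 0 simulations called an unshifted list, a list shifted by 0.1 on the log2 scale was called in 46 with the preset correlation and in 0 with an estimated one. The simulated genes varied independently, so these counts do not apply to lists whose members vary together, such as G1/S and heat shock with estimated correlations of 0.245 and 0.251.

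Alternatives were the replicate number as a block, a prior without trend, a robust prior, clusters brighter than the median, median centring, quantile normalization, leaving out each array in turn (the lone array then being assumed to vary like the other group), least squares without shared variance, treat against 1.2-fold, named genes only, other set tests and the mean over a gene's clusters. Array weights, 1 cluster per distinct row of values (65840 rows) and the main p-values adjusted over named genes were added after seeing the data.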

Results

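Gene expression was measured on 4 Affymetrix Human Transcriptome Arrays with total RNA from hCMEC/D3 cells, an immortalized human brain microvascular endothelial line used as a model of the blood-brain barrier. RNA was taken 48 h after transfection. The 2 arrays titled E came from cells that received a plasmid for overexpression of CLDN5, the gene of claudin-5, the most abundant claudin of brain endothelial tight junctions. The 2 arrays titled NC have conflicting descriptions: their treatment label names a CLDN5 siRNA, whereas other text of the submitters points to control cells. This conflict was not resolved here, so the groups are called E and NC, and E versus NC may stand for overexpression against control or against knockdown. The median log2 signal over 67528 transcript clusters, the array's units of about 1 transcribed locus each, was 4.38 and 4.39 on the E arrays and 4.33 and 4.45 on the NC arrays. The small number of arrays limits the precision of every value, and as no label says that the 2 arrays of a group came from separate cultures, p-values measure only the spread between these arrays, which may be technical.

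The first comparison asked whether the targeted gene differed between the groups. CLDN5 signal was almost equal, at 6.48 ± 0.073 in E and 6.36 ± 0.061 in NC (log2, mean ± SD, n = 2 each). The 4 values were 6.43 and 6.53 on the E arrays and 6.31 and 6.40 on the NC arrays, so both E arrays lay above both NC arrays by a small margin. The E to NC ratio was 1.09, with a 95% confidence interval of 0.932 to 1.28, and did not pass the test (log2 difference 0.13, SE 0.088, adjusted p = 1 in limma). An increase of CLDN5 signal above 1.28-fold thus lay outside the interval. The table holds 1 summary value for CLDN5, the cluster TC22000498.hg.1, and does not show which part of the transcript its probes read.

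Other barrier genes differed by small amounts. Occludin (OCLN), a transmembrane protein of tight junctions, was 1.24-fold higher in E and CLDN1, another claudin, 1.21-fold higher, on both E arrays, and neither passed the test (adjusted p = 1 for each, limma). CDH5, the VE-cadherin of endothelial adherens junctions, was 1.09-fold and endoglin (ENG), an endothelial TGF-beta coreceptor, 1.18-fold higher, also without passing. OCLN, CLDN1, CDH5 and ENG were named for the smallest unadjusted p of their lists, so they do not stand for the lists. Of 25 measured tight junction genes, 8 were higher and 5 lower on both E arrays. Of 31 genes of adherens junctions and endothelial identity, 6 were higher and 9 lower. In both lists 0 members passed the threshold over all clusters and 0 when adjusted over the list alone. The tight junction list had a median log2 difference of -0.01 (camera adjusted p = 0.862), although its mean (0.02) and test pointed up, and the endothelial list had a median of -0.03 (adjusted p = 0.447). The mixed test of fry, which asks whether members differ in either direction, gave these 2 lists adjusted p-values of 0.0127 and 0.00639. At the adjusted threshold this test passed 18 of the 26 lists. In 100 sets of 26 random lists matched on signal it passed 0 to 9, with a median of 4. The random lists were drawn gene by gene and set no firm level for these 2 lists. The mixed test by itself thus does not show that barrier genes differ. The 29 measured blood-brain barrier transporters had a median of 0.01 (adjusted p = 0.518), with 0 members past either threshold. Among those higher in E, the largest values were those of the taurine transporter SLC6A6, 1.19-fold higher, and the nucleoside transporter SLC29A1, 1.12-fold higher. Only 12 of 25 tight junction, 18 of 31 endothelial and 16 of 29 transporter genes had a log2 signal above 6.27, the upper quartile of all clusters. Dim members such as ABCB1 (4.65) and MFSD2A (4.32) lay near the median of 4.38, where a difference could hardly be seen.

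**Figure D1:**
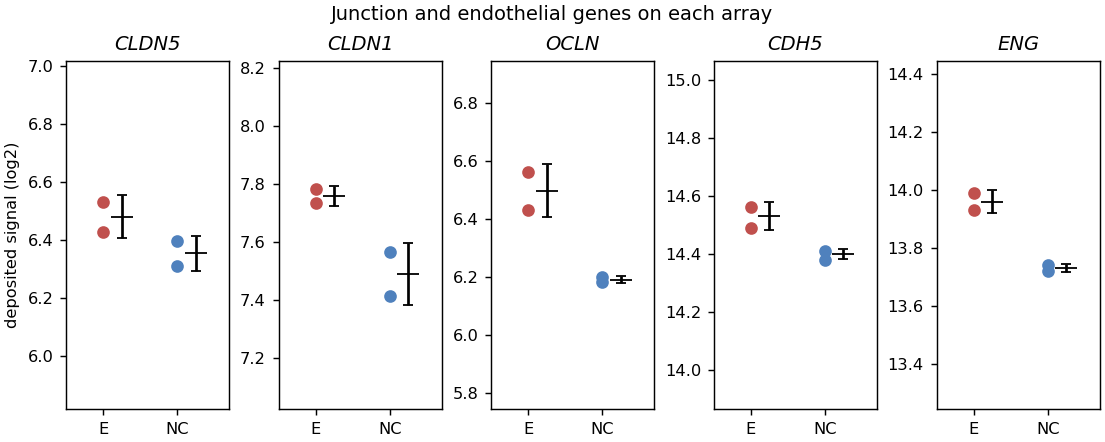
Deposited log2 signal (vertical axes, each spanning the same range around its gene) of CLDN5, CLDN1, OCLN, CDH5 and ENG on the 2 E arrays (red) and 2 NC arrays (blue), with the group mean ± SD in black. In each gene both E arrays lie above both NC arrays, by at most 0.31 between the group means, and none of the 5 genes passed the test. The genes other than CLDN5 are shown for the smallest unadjusted p of their lists, in which other members were lower in E.

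The second comparison covered all transcripts. No single gene was shown to change between E and NC, as 0 of 67528 clusters passed an adjusted p of 0.05 in limma, with a smallest adjusted p of 0.103. At an unadjusted p under 0.05 there were 2942 clusters, 1604 higher and 1338 lower in E, against 3376.4 given by chance. This count was 8745 without NC 1, 7063 without NC 2, 1269 without E 1 and 1232 without E 2, and after quantile normalization its balance turned to 1721 higher and 1872 lower. Per-cluster least squares without shared variance also passed 0, with 3215 at the unadjusted level, and limma's treat against 1.2-fold passed 0, with 354. In simulations with variances drawn from their fitted prior, 89.2% of 4-fold differences were recovered at the adjusted threshold and 0% of 2-fold ones. In that simulated fit over all clusters, differences of 2-fold or less were thus not detectable singly. The simulated data gave more unchanged clusters at 2-fold than the real arrays gave in total, so these shares may not hold for the arrays.

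The largest differences belonged to a few genes outside the barrier lists. Amelotin (AMTN), a secreted protein of enamel formation, had a log2 signal of 8.28 ± 0.037 in E and 6.61 ± 0.204 in NC (mean ± SD, n = 2 each), a 3.19-fold higher value (SE of the log2 difference 0.118, adjusted p = 0.175, limma). POTEC, a member of the primate-specific POTE ankyrin domain family, was at 5.71 ± 0.011 in E and 7.67 ± 0.216 in NC, a log2 difference of -1.96 (SE 0.123, adjusted p = 0.121, limma). At 2-fold and an unadjusted p under 0.05 simulated data gave 131 to 136 unchanged clusters, and the other splits of the 4 arrays into pairs 38 and 43. The simulated data thus gave more such clusters than any split of the real arrays, and set no chance level. By this rule E versus NC gave 55 clusters, 15 higher and 40 lower in E. The balance depended on single arrays, with 46 of 94 higher in E without E 1 and 113 of 199 without NC 2. Only 4 of the 55 carry the symbol of a single gene: AMTN, POTEC, the CXADR pseudogene CXADRP3 and the immunoglobulin segment IGHD3-22, the last 2 named after their values were seen. When only the 22465 named genes were fitted, which also refitted the variance prior, 3 passed in limma, namely CXADRP3 (log2 difference -1.88, adjusted p = 0.0173), TMPRSS15, the gene of enteropeptidase (-0.93, adjusted p = 0.0356), and POTEC (adjusted p = 0.0421), and AMTN did not (adjusted p = 0.0574). With the p-values of the main fit adjusted over the same genes, an alternative chosen after seeing the data, 0 passed (smallest adjusted p = 0.127).

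POTEC and CXADRP3 belong to a group of loci with POTE or CXADR symbols, which was looked at after their values were seen. All 16 clusters whose listed symbols are POTE or CXADR genes were lower on both E arrays than on both NC arrays, with a median log2 difference of -0.52. The difference was 2-fold or more in 5 of them, on chromosomes 15, 18 and 21 by their cluster names. CXADR itself, the coxsackievirus and adenovirus receptor of epithelial and endothelial junctions, had a log2 difference of -0.55 (SE 0.090, adjusted p = 0.924, limma), POTEH one of -0.49 and POTEA one of -0.08. The CXADR signal, 4.25 in E and 4.81 in NC, lay close to the median of all clusters. None of the 16 passed the threshold over all clusters. The chromosome 15 clusters listed as POTEB or POTEB2 were almost alike (-1.67 and -1.66), and the chromosome 21 cluster lists both POTED and POTEC. The 16 clusters may thus not be separate measurements, and whether they share probes was not analysed here.

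**Figure D2:**
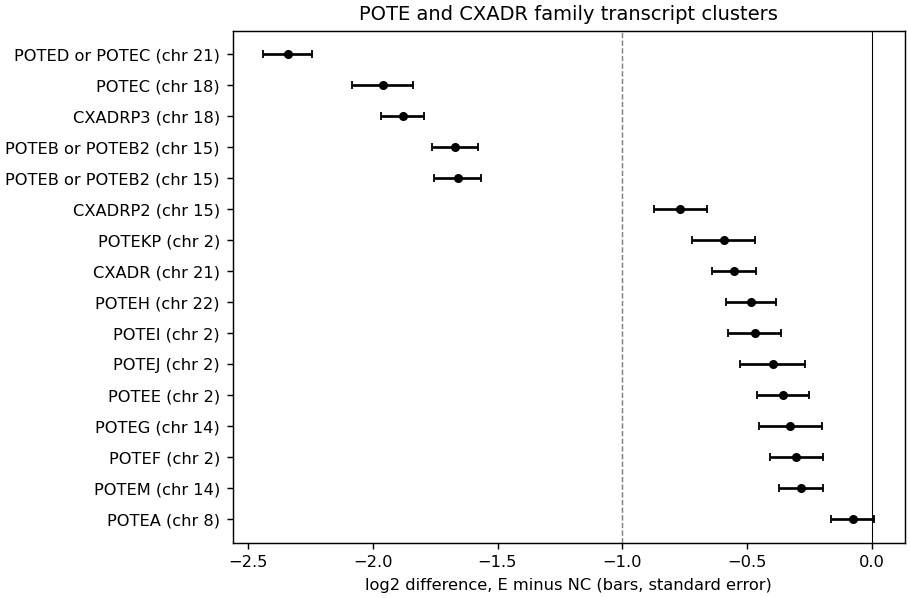
Log2 difference (horizontal axis, E minus NC, with its standard error) of the 16 POTE and CXADR family clusters, each with its listed symbols and the chromosome in its cluster name; the dashed line marks a 2-fold lower value. All 16 points lie below 0, from -2.34 to -0.08.

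The third comparison asked whether gene groups shifted together. Interferon response genes rose as a group in E relative to all other genes, although the size was small: the median log2 difference of 44 measured members was 0.07, a 1.05-fold difference (camera adjusted p = 0.000156). The call was lost in camera with an estimated correlation (adjusted p = 0.784). This loss cannot decide, as that setting called the list in 0 of 50 simulations in which it was shifted by 0.1. The directional test of fry, which asks whether the members moved 1 way, gave an adjusted p of 0.0266. No member passed over all clusters or adjusted over the list alone, 18 were higher and 3 lower on both E arrays, and 7 had an unadjusted p under 0.05, all higher. They include IFI6, an interferon-induced mitochondrial protein (1.40-fold), and OAS2, an oligoadenylate synthetase activated by double-stranded RNA (1.33-fold), and, named after their values were seen, IFI44L (log2 difference 0.43), IFI27 (0.34) and the ISG15 protease USP18 (0.27). Widely used interferon markers that lay near the array's median signal had differences of 0.01 (ISG15), 0.05 (MX1) and 0.12 (IFIT1). Leaving out array NC 2 gave an adjusted p of 0.059, although the list median was 0.0667 (bootstrap SE of the median 0.0281) against 0.0682 (0.0172) with all arrays, while the median of the other genes was 0.0213 against 0.0044. The mixed test of fry passed 18 of the 26 lists. It compares a list with no other genes, and in 100 sets of 26 random lists matched on signal, drawn after seeing the data, it passed 0 to 9 lists with a median of 4. The random lists were drawn gene by gene, whereas members of some lists vary together (estimated correlation 0.669 for G2/M). The 2 counts thus cannot be weighed against each other.

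Genes of the G1/S phase and of the heat shock response were also called higher in E as groups, and both calls were lost in camera with an estimated correlation (adjusted p = 0.784 for each). The simulations do not bear on this loss, since their genes varied independently. These 2 lists had estimated correlations of 0.245 and 0.251, above the preset 0.01. The 38 measured G1/S genes had a median log2 difference of 0.06 (camera adjusted p = 0.00327), with 17 higher and 3 lower on both E arrays, and this list was also called in 1 of the other 2 splits of the arrays into pairs. The replication licensing factor CDC6 was 1.24-fold and the flap endonuclease FEN1 1.26-fold higher, while the primase subunit PRIM1, named after its value was seen, had a log2 difference of -0.18. The 17 measured heat shock genes had a median of 0.08 (adjusted p = 0.0114), with 8 higher and 0 lower on both E arrays, among them the co-chaperone DNAJA1 (1.25-fold) and HSP90AA1, an HSP90 chaperone (1.16-fold). Both lists are bright, with 37 G1/S and 15 heat shock genes above the upper quartile of all clusters. Clusters brighter than the median had a median log2 difference of 0.0162, against 0.00303 over all clusters. A comparison with random lists matched on signal was not run for these 2 lists. In both lists 0 members passed over all clusters or adjusted over the list alone. Both calls were also lost with fry (adjusted p = 0.351 for each), after centring each array on its median (0.0879 and 0.164), after quantile normalization (0.18 and 0.198) and without NC 2 (0.665 and 0.602), and that of heat shock without E 1 (0.0546).

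Other proliferation genes did not shift as a group. The 41 G2/M genes had a median log2 difference of 0.03 (adjusted p = 0.705), with the proliferation marker MKI67 at 0.78 times its NC level and CDC20, an activator of the anaphase-promoting complex, higher in E by 0.26 on the log2 scale. This list depended on the NC arrays, since it was called higher in E without NC 1 (adjusted p = 0.000873) and lower without NC 2 (adjusted p = 0.0161), and it was called in both other splits of the 4 arrays into pairs. The 12 measured replication-dependent histones had a median of -0.02 (adjusted p = 0.705), with H2BC11 at -0.24 and H2BC9 at 0.22. The 29 ribosomal protein genes had a median of 0.05 (adjusted p = 0.0773), with RPL7 at 0.14 and RPL19 at 0.09, and were called higher in E without NC 1 (adjusted p = 0.0288). In these 3 lists 0 members passed over all clusters or adjusted over the list alone.

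Adhesion and motility genes did not pass as groups either. The 38 adhesion molecules had a median log2 difference of 0.03 (adjusted p = 0.329), with syndecan-4 (SDC4) 1.21-fold higher in E and the integrin subunit ITGB8 at 0.83 times its NC level. The 36 genes of migration and matrix remodelling had a median of 0.01 (adjusted p = 0.518), with the collagenase MMP1 1.28-fold and the matrix protein SPARC 1.16-fold higher. The 30 YAP and TGF-beta targets had a median of 0.03 (adjusted p = 0.157), and the 28 immediate early genes one of -0.0017 with a mean of 0.07 and a test that pointed up (adjusted p = 0.102). Both of these lists were called higher in E without NC 1 (adjusted p = 0.0288 for each). CCN2, a matricellular growth factor target of YAP and a member of both lists, was 1.48-fold higher in E and was the single member of either list to pass when adjusted over the list alone. KLF2, a flow-responsive endothelial transcription factor, was 1.22-fold higher, and AJUBA, a LIM-domain scaffold of cell junctions, was at 0.84 times its NC level. The other lists of this paragraph had 0 such members.

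Stress and metabolic lists held a few single genes with larger values. TNFAIP3, the deubiquitinase A20 that limits NF-kappaB signalling, was 1.58-fold higher in E, and SCD, the stearoyl-CoA desaturase, was at 0.65 times its NC level. Each was the single member of its list to pass when adjusted over the list alone, and neither passed over all clusters (adjusted p = 0.607 and 0.855, limma). The adjustment over a list alone does not correct for the 26 lists, of which 6 had such a member. As a group the 30 NF-kappaB genes had a median of 0.02 (adjusted p = 0.705), with NFKB1 at 0.91 times its NC level, and the 22 cholesterol genes one of 0.00054 with a mean of -0.03 and a test that pointed down (adjusted p = 0.566), with HSD17B7 at 1.13-fold. The 25 p53 targets had a median of 0.03 (adjusted p = 0.157, and 0.00241 without NC 1, higher in E), with the cell cycle inhibitor CDKN1A (1.33-fold) and the apoptosis effector BAX (1.32-fold) as the largest. The 31 unfolded protein and integrated stress response genes had a median of 0.03 (adjusted p = 0.325), with the cystine transporter SLC7A11 (1.29-fold) and the chaperone HSPA5 (1.18-fold). The 31 hypoxia and glycolysis genes had a median of 0.0044 (adjusted p = 0.705), with NDRG1 at 1.14-fold and ANGPTL4 at 1.26-fold. The p53, unfolded protein and hypoxia lists had 0 members past either threshold.

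Of 4 signalling pathways that the study itself names for these samples, which makes their lists no independent evidence, 0 passed as a group. The 45 JAK-STAT genes had a median log2 difference of 0.01 (adjusted p = 0.604). IL7R, the interleukin-7 receptor chain, was 1.92-fold higher in E, the largest value of any list, and the single JAK-STAT member to pass when adjusted over the list alone, but not over all clusters (adjusted p = 0.267, limma). IFNGR2 was 1.16-fold higher. The 54 PI3K-Akt genes had a median of -0.01 (adjusted p = 0.421), with the kinase subunit PIK3CG at 0.75 and the Akt phosphatase PHLPP1 at 0.85 times their NC levels. The 55 Wnt genes had a median of 0.0036 and a test that pointed down (adjusted p = 0.914), with the Wnt antagonist DKK1 1.10-fold and the receptor FZD7 1.14-fold higher, FZD7 at a signal below the array median. The 37 Notch genes had a median of -0.04 (adjusted p = 0.157), with SNW1 at 1.13-fold and the coactivator MAML3 at 0.89 times its NC level. The PI3K-Akt, Wnt and Notch lists had 0 members past the threshold over all clusters or adjusted over the list alone.

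Markers of other cell types did not pass as groups with all arrays. The 30 epithelial and lung carcinoma markers had a median log2 difference of 0.0018 (adjusted p = 0.869), the 22 pericyte, smooth muscle and fibroblast markers one of -0.01 with a mean of 0.0012 (0.705), the 21 astrocyte and neuron markers one of 0.02 with a mean of -0.01 and a test that pointed down (0.705), and the 21 blood cell markers one of 0.01 (0.705). The blood cell list was called higher in E without NC 2 (adjusted p = 0.0185), and it was also called in both other splits of the 4 arrays into pairs, and the epithelial list in 1 of them. Only 4, 3, 1 and 1 of these markers had a log2 signal above 6.27, the upper quartile of all clusters, among them ALDH1A1 (0.09, and -0.0111 after quantile normalization), ANPEP (0.21), RGS5 (-0.20), GJA1 (-0.30) and CD68 (0.21). GJA1, the gap junction protein connexin 43, was the single one to pass when adjusted over its list alone. Dim members such as AKR1C2 (0.15), FABP7 (-0.11) and CD79A (0.17) had a signal close to or below the array median.

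**Figure D3:**
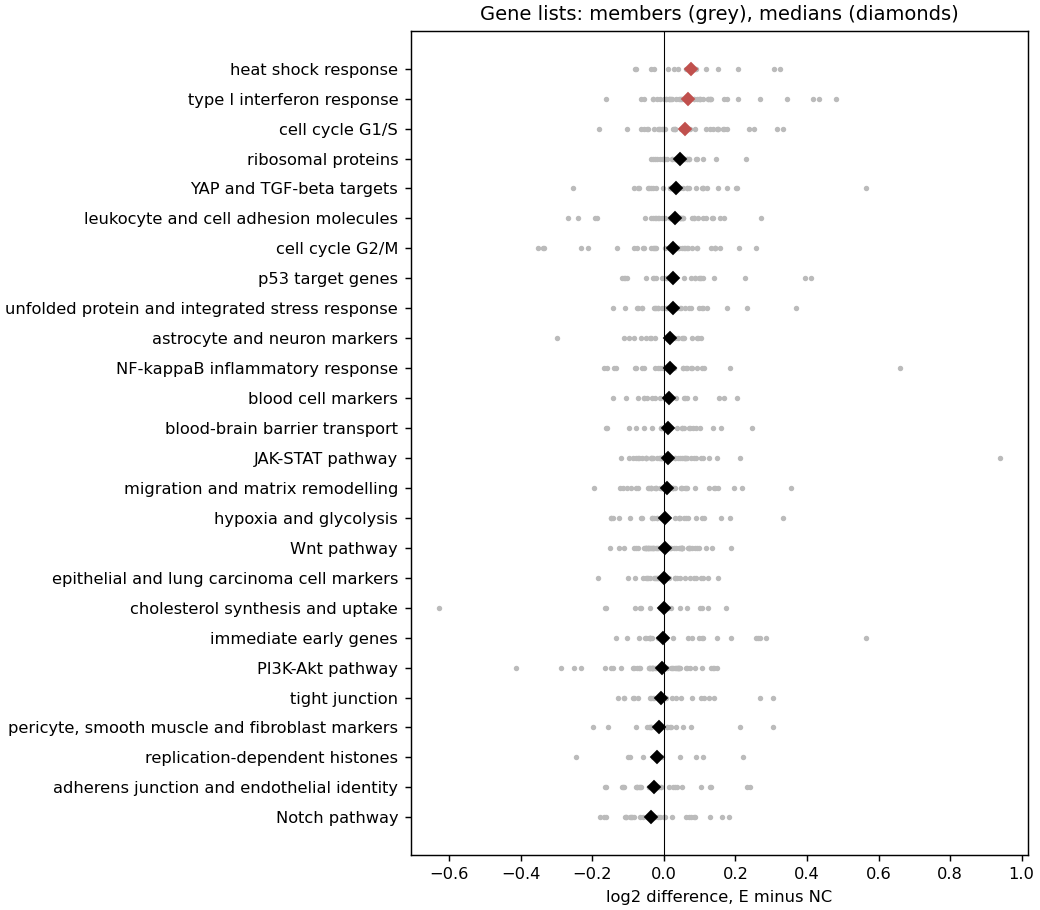
Log2 difference (horizontal axis, E minus NC) of each measured member (grey) of the 26 gene lists, with the list median as a diamond, red where the camera adjusted p was under 0.05. The list medians lie between -0.04 and 0.08, and 3 lists passed.

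The 4 arrays resembled each other closely, and the NC arrays were the least alike. NC 1 and NC 2 differed by 2-fold or more in 592 clusters (Pearson r = 0.9944 across clusters, which are not independent replicates), against 78 for the E arrays (0.9975) and 224 to 272 for a pair with 1 array of each group (0.9959 to 0.9965). The first principal component, with 50.4% of the variance, set NC 1 and NC 2 at its opposite ends with both E arrays between them. The second, with 29.2%, set the E arrays (18.6 and 20.18) apart from the NC arrays (-22.46 and -16.32). Both E arrays lay beyond both NC arrays in 20730 clusters, or 30.7%, where 33.3% is the share given by chance.

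**Figure D4:**
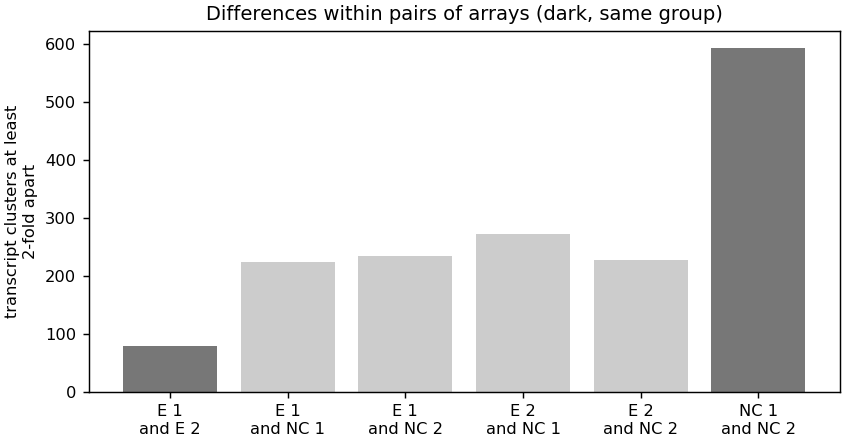
Number of transcript clusters (vertical axis) that differ by 2-fold or more within each pair of arrays, dark bars for pairs of the same group. The NC pair stands highest at 592 clusters and the E pair lowest at 78.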

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

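Array weights, the count over distinct rows of values and the main p-values adjusted over named genes were chosen after seeing the data. Camera with an estimated correlation called the simulated shifted interferon list in 0 of 50 simulations, so the loss of the interferon call in that setting cannot decide. The simulated genes varied independently, so this does not extend to G1/S and heat shock, whose members vary together. No alternative passed a transcript cluster at the adjusted threshold except the test of named genes only, which refitted the variance prior and passed 3; the main p-values adjusted over the same genes passed 0. CLDN5 stayed higher in E and short of the threshold throughout, from 0.07 to 0.18 (log2). The count at 2-fold and an unadjusted p under 0.05 ran from 44 to 57 with all arrays and from 73 to 199 when 1 array was left out (94 without E 1, 140 without NC 1, 199 without NC 2, of which 46, 55 and 113 were higher in E). The replicate numbers are not known to pair the arrays (deviations of same-numbered arrays correlate at 0.0573 across clusters); with the number as a block 0 clusters passed (3137 unadjusted), 57 were at 2-fold, 3 lists passed and no call changed. The number of lists past the threshold, 3, became 1 after median centring, 1 after quantile normalization, 1 with fry (18 with its mixed test of either direction) and 0 with an estimated correlation, and 2 to 8 when 1 array was left out, with 8 without NC 1. The adjusted p of G1/S was 0.0879, 0.18, 0.351 and 0.784 in these 4 settings and 7.7e-05 to 0.665 leaving 1 array out; that of heat shock was 0.164, 0.198, 0.351 and 0.784, and 0.000525 to 0.602. The interferon list was lost with an estimated correlation (0.784) and without NC 2 (0.059; 0.000525 to 0.059 leaving 1 array out), where its median was 0.0667 against 0.0682. G2/M was called higher in E without NC 1 (0.000873) and reversed without NC 2 (lower in E, 0.0161), with 0.000873 to 0.809 leaving 1 array out, and ALDH1A1 reversed after quantile normalization (-0.0111). Without NC 1 the p53 (0.00241), immediate early, YAP and TGF-beta and ribosomal protein lists (0.0288 each) were called higher in E, and without NC 2 the blood cell markers (0.0185). Of the other 23 lists, 315 of 322 values stayed uncalled, and of 645 named gene values 644 kept their direction. The cause was not tested for any of these changes. A fit without 1 NC array takes its spread from the E arrays alone, whose residual SD was 0.126 (log2), against 0.192 for the NC arrays. Calls and counts without an NC array are thus measured against this narrower spread and 1 remaining NC array. Dim clusters are limited by background, and 2 arrays per group by their number.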

Other observations

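The tests of the POTE and CXADR loci, of a level-dependent shift, of array NC 2, of exchanged labels and of the splits for 2-fold clusters were chosen after their results were seen. Further genes, also chosen afterwards and not a full ranking, were looked at. Higher in E were the ephrin ligand EFNB2 (1.75-fold), the LIM-domain protein PDLIM1 (1.71-fold), LCE2A (1.69-fold) and KPRP (1.565-fold). The phospholipase PLCB4 was 1.49-fold and the quinone reductase NQO1 1.34-fold higher. The EFNB2 signal, 5.11 in E and 4.31 in NC, lay close to the median of all clusters. The teneurins TENM3 and TENM1 were at 0.62 and 0.65 and the hormone STC1 at 0.71 times their NC levels. None passed the adjusted threshold over all clusters in limma (adjusted p = 0.323 to 0.924), and each lay on 1 side on both E arrays.

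All 16 POTE and CXADR clusters had a lower signal on both E arrays. A lost segment of chromosome 21 is argued against by the 21 other named genes between POTED and TMPRSS15, whose median log2 difference was -0.0314 (bootstrap SE of the median 0.0434). Several of them lay below the median signal of 4.38, where a loss could hardly be seen. The brightest were USP25, HSPA13 and MIR99AHG, at -0.03, -0.05 and -0.14, and the lowest value of all 21 was -0.282. One outlying array is argued against as well, since the family median of -0.52 stayed at -0.415 or further from 0 whichever array was left out. Probes shared between copies, so that 1 changed transcript is read several times, cannot be told apart from separate changes, because clusters 2-fold lower lie on 3 chromosomes, which both would give. The transfection, as a biological explanation, stays open and untested by any independent measurement.

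The interferon list rose by a small amount in E, and the treatment of the cells, as a biological explanation, stays open and untested. Camera with an estimated correlation gave an adjusted p of 0.784, but it called the simulated shifted list in 0 of 50 simulations and cannot decide. A level-dependent shift between arrays is argued against, as the list's median lay at percentile 99.99 of 10000 random lists matched on signal and the call held after quantile normalization (adjusted p = 0.0024). A part played by NC 2 alone cannot be told apart, since without it the median was 0.0667 (bootstrap SE of the median 0.0281) against 0.0682 (0.0172), but the median of the other genes was 0.0213 against 0.0044 and the adjusted p was 0.059. The 3 possible splits of 4 arrays are too few to weigh chance: the real split called 3 lists and the highest other split 4, so that 2 of 3 splits called at least 3. The interferon list itself was not called in the other splits (camera adjusted p = 0.578 and 0.515, medians 0.0141 and 0.000398), which with so few splits does not weigh chance either. For clusters at 2-fold, likewise too few, the real split gave 55 and the highest other 43, and 1 of the 3 splits reached 55.

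CLDN5 signal was almost equal in a comparison built around that gene. No regrouping of the 4 arrays gives a large CLDN5 difference, because the whole range of CLDN5 was 0.221 on the log2 scale. This cannot decide whether labels were exchanged, since CLDN5 signal on this array may not report the treatment. Probes that lie outside the transcript made from the plasmid could hide an increase, and this cannot be told apart here, since the table has 1 summary value for the gene. A weak or lost overexpression at 48 h, and arrays of cells outside the described treatment, were not tested.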
